A study of Mus musculus with 46 samples.

How the data were processed

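RNA was measured by sequencing in 46 libraries of mouse EPSCs and cells derived from them. Per the labels' protocols, RNA was extracted with TRIzol, libraries were prepared with 2 total RNA kits (a stranded SMARTer kit and a VAHTS kit), and sequencing was done on a NovaSeq 6000; which kit made which library was not given in the sources used here. Per the submitters' processing notes, reads were handled with FastQC 0.12.1, Trim Galore, STAR 2.7.11b, Subread and DESeq2 on the mm39 build; the gene annotation and the strand setting were not given in the sources used here. Genes that overlap or run antisense to each other therefore cannot be told apart, and near-identical copies (the Zscan4, Eif1ad and Usp17l families and histone genes) are uncertain. The 7 tables the authors deposited hold raw counts per gene, as whole numbers with a different total in each library. Every column matched a single sample title, so 0 columns were left out. Each table had 21812 genes, of which 19 repeated symbols were left out of the EPSC table. The Virma table's column names carry the word "input", and nothing else in the labels says how those libraries differ in kind.

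Groups came from the sample titles. The labels gave no culture, batch or date, and no replicate pair differed by less than sampling noise (chi-square per degree of freedom 1.21 to 20.6 over 47 pairs), so each library counted once. Pairs of the actinomycin D table lay at 1.21 to 1.32, little above sampling noise. Their replicates may therefore be technical repeats, and p-values from that table may measure little more than counting error. Total counts ran from 14927080 to 22280769 in the actinomycin D table, 7267487 to 14824609 in the embryoid table, 6854433 to 10005196 for EPSC, 12788803 to 15973967 for the sorted cells, and 10590199 to 12250333, 8516622 to 12164428 and 8160276 to 8643434 in the Virma, Mettl3 and Igf2bp3 tables. Depth varied most in the embryoid table. A level of 3 counts, the limit that a count of 0 allows, was the floor for genes without counts. Folds against a group at 0 are lower bounds against 3 counts in each library of the group, and for 1 to 3 counts in a group the ratio is given with an exact 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

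Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, a filter keeping genes with a count of 10 in enough libraries and 15 in all, a robust quasi-likelihood fit) on the counts as deposited, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each perturbation, the sorted fractions and the embryoid parts were fitted on their own table. All 16 actinomycin D libraries entered a fit with a mean for each state and time for the comparison at 0 h, and a fit with an intercept and a slope per hour for each state for the decay comparisons. Because each library is scaled to its own counts, slopes are relative to the average transcript. Log2 changes are edgeR's, with a prior count of 2, and each SE was derived from the estimate and its test statistic. Comparisons across tables joined libraries on gene names and were made with the knowledge that table and group coincide; values set side by side across tables carry the same limit.

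A total of 27 gene lists was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists of a comparison, and again with a correlation estimated for each list. The list of 15 small structural RNAs had 0 members among the genes and gave no result. The sets taken from the sorted fractions and the perturbations (adjusted p under the threshold; at least 1 log2 unit for the sorted fractions) were tested in other tables in the same way. The gene lists, tests, main alternatives and the rule for named genes were set before the data were examined. The rule named the targeted gene; the 8 largest rises and 8 largest falls below the threshold with a mean of at least 10 CPM, groups that do not overlap, and a gene symbol that is no predicted locus name; up to 4 members of each list by adjusted p; and Gata6, Gata4, Sox17, Sox7, Pdgfra, Nanog, Pou5f1 and Sox2 in every comparison. For slopes the rule had no condition on overlap. Not every gene it named is printed, and results of some genes are not reported here.

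Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, a filter of 1 CPM, the replicate number as a block, 3 h against 0 h alone, slopes without the 3 h libraries, leaving out each library in turn, and other log2 minimums. Chosen after seeing the data were scaling to library totals in every comparison and to ribosomal protein genes in all but the decay slopes, the fits without the EPS 3 h libraries, 2 h against 0 h, a crossed pairing, list tests of slopes without 3 h, and leaving out single embryoid libraries.

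The fits were tested on simulated counts with the real means and library sizes and 200 changed genes. At a log2 change of 1, edgeR recovered 66% of changed genes for Virma, 80% for Mettl3 and for Igf2bp3, 53% for the sorted fractions, 69% for the embryoid and 85% for the states at 0 h. At a slope of 0.5 it recovered 76% in EPS, 82% in PrEdiff and 67% of slope differences. False calls were 2% to 13.3% of calls over the comparisons, highest for PrE-E against EPSC, and over the threshold in several comparisons within and across tables. Gene length and GC content came from an annotation of another build than the authors', by symbol, for 21577 of 21812 genes, and no coordinates are given.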

Results

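The series measured RNA in mouse EPSCs, pluripotent stem cells kept in conditions that widen their developmental potential, and in the primitive endoderm (PrE) and epiblast cells made from them. PrE is the lineage that separates from the epiblast in the blastocyst and later forms yolk sac endoderm. The stated questions were the transcriptomic states of these cells and the stability of RNA across states, and the series title names N6-methyladenosine (m6A), an abundant internal modification of mRNA. The 46 libraries fell into 19 groups in 7 count tables. One table held EPSC (2 libraries), and another CD140+ (PrE-E) and CD140- (EPI-E) cells from induced cultures (2 each). A further table held EPI and VE parts of embryoids, structures grown from EPSCs together with GBL-1 cells (6 each). EPSCs (EPS) and PrE-induced cells (PrEdiff) were sampled after 0, 1, 2 and 3 h of actinomycin D, an inhibitor of transcription (2 each). The last 3 tables held PrE-induced cells labelled Virma wild type (WT) and cKO, Mettl3 WT and cKO, and siNC and siIgf2bp3 (2 each). Total counts per library ran from 6854433 to 22280769. Changes are log2 values ± SE, expression values are CPM (counts scaled with TMM factors) ± SD, and n = 2 libraries per group unless given otherwise. "Rose" and "fell" are used only for genes below the adjusted p threshold of 0.05 in edgeR's quasi-likelihood test. The labels did not say that replicates were separate cultures, so p-values measured the spread between these samples, which may be technical.

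Virma, a scaffold subunit of the m6A writer complex, fell from 108 ± 2.19 to 61.1 ± 9.25 CPM in the libraries labelled Virma cKO (-0.82 ± 0.12, adjusted p = 1.12e-06). The transcription factors that specify PrE fell together. Gata6 went from 87.5 ± 2.86 to 4.70 ± 0.495 CPM (-4.22 ± 0.19) and Gata4 from 107 ± 1.94 to 8.06 ± 0.509 (-3.72 ± 0.16). Sox7 went from 76.6 ± 9.09 to 3.57 ± 0.906 CPM (-4.42 ± 0.21) and Sox17 from 29.3 ± 4.03 to 4.08 ± 0.908 (-2.84 ± 0.28). Pdgfra, the receptor subunit that marks PrE cells, fell from 476 ± 13.3 to 87.1 ± 7.14 CPM. Among pluripotency factors, Nanog (-1.06 ± 0.19) and Pou5f1 (-0.75 ± 0.08) fell by less, and Sox2 was -0.10 ± 0.10 (adjusted p = 0.491), turning to 0.30 when libraries were scaled to ribosomal protein genes and to 0.07 when scaled to library totals. In all, 4348 of 13113 tested genes changed, 1984 rising and 2364 falling.

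Of the PrE regulators, 11 fell and 0 rose of 12 tested (12 and 0 adjusted over the list alone), with a median change of -3.06 (camera adjusted p = 8.21e-48, and adjusted p = 0.0826 with an estimated correlation). Dab2, an endocytic adaptor of extraembryonic endoderm, fell by 17.0-fold. Basement membrane genes were lower (11 fell and 1 rose of 14, median -1.51, adjusted p = 4.40e-58, and adjusted p = 0.0826 with an estimated correlation). The laminin chain genes Lama1 (-4.31 ± 0.07), Lamc1 (-2.48) and Lamb1 (-2.27) and the type IV collagen gene Col4a1 (-2.17) were among them. Visceral endoderm genes were lower (3 fell and 1 rose of 11, median -0.99, adjusted p = 2.18e-17, and adjusted p = 0.0826 with an estimated correlation). Cubn, which encodes the endocytic receptor cubilin, fell from 1040.1 ± 14.03 to 38.5 ± 3.34 CPM and Lrp2, its partner megalin, by 23.2-fold. The anterior visceral endoderm list had a median of -1.16 with 3 of 6 falling, Dkk1 among them (-4.12 ± 0.32; adjusted p = 0.0142, and adjusted p = 0.238 with an estimated correlation). The parietal endoderm list had a median of -0.20 and a mean of -0.93, with 3 members rising and 3 falling (adjusted p = 1.15e-07, and adjusted p = 0.101 with an estimated correlation), and its median turned to 0.20 with ribosomal scaling.

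Of the naive pluripotency genes, 11 fell and 1 rose of 16 tested (12 and 1 adjusted over the list alone) at a median of -1.12 (adjusted p = 1.91e-14, and adjusted p = 0.0826 with an estimated correlation), Klf5 (-1.69) among them. Core pluripotency genes were lower (6 of 10 fell, median -0.36, adjusted p = 6.81e-06, and adjusted p = 0.129 with an estimated correlation), a median that became 0.04 with ribosomal scaling. Proliferation genes were lower (12 of 14 fell, median -0.46; adjusted p = 6.81e-06, and adjusted p = 0.101 with an estimated correlation). So were glycolysis and hypoxia genes (8 fell and 1 rose of 13, median -0.50; adjusted p = 3.82e-07, and adjusted p = 0.101 with an estimated correlation). Ribosomal protein genes were lower too (72 fell and 1 rose of 82, median -0.41; adjusted p = 1.20e-17, and adjusted p = 0.101 with an estimated correlation). Replication-dependent histone genes had a median of -0.60, with 27 of 57 falling (adjusted p = 2.03e-05, and adjusted p = 0.356 with an estimated correlation). With ribosomal scaling these last 4 medians were -0.06, -0.10, -0.01 and -0.21, with 2, 5, 17 and 10 genes falling and 1, 2, 13 and 4 rising. That scaling sets the ribosomal list near 0 whatever the data, so it tests these genes nowhere.

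The feeder fibroblast markers made up 0.105% and 0.104% of the counts of the WT libraries and 0.291% and 0.287% of those of the cKO libraries. All 12 markers rose (median 1.26, adjusted p = 9.35e-24, and adjusted p = 0.0826 with an estimated correlation). Col3a1, a fibrillar collagen gene, went from 271 ± 6.67 to 720.4 ± 5.71 CPM. Of the p53 target genes, 11 rose and 1 fell of 15 tested (13 and 1 adjusted over the list alone), median 0.81 (adjusted p = 7.18e-06, and adjusted p = 0.101 with an estimated correlation). They included the cell cycle inhibitor gene Cdkn1a (1.23 ± 0.17) and the exonuclease gene Aen (1.07). Of the neural ectoderm genes, 2 rose and 0 fell of 5 tested (3 and 0 adjusted over the list alone), median 0.81 (adjusted p = 0.0281, and adjusted p = 0.372 with an estimated correlation). Igf2bp3, an RNA-binding protein described as an m6A reader, fell from 99.5 ± 10.97 to 41.6 ± 4.04 CPM, while Wtap (0.59) and Ythdf2 (1.13) rose. The lists of m6A writers (-0.05, adjusted p = 0.974) and of erasers and readers (median 0.04 and mean -0.05, adjusted p = 0.974) were not called. The other lists were not called, among them interferon response (1.62, adjusted p = 0.128) and the trophoblast list, where the test pointed lower (median 0.78, adjusted p = 0.898). The scaling decided the balance of calls: the median of all genes was 0.02 in the fit used, 0.20 with library totals and 0.43 with ribosomal scaling, and the split became 3001 rising and 1491 falling, and 4867 rising and 750 falling.

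In the libraries labelled Mettl3 cKO, the counts of Mettl3, the catalytic subunit of the writer complex, did not differ from the WT (36.3 ± 1.55 to 36.0 ± 1.57 CPM, -0.02 ± 0.11, adjusted p = 0.978). Gene counts would not show a deletion that left most exons transcribed, so every direction below is that of libraries labelled cKO. Gata6 fell from 239.9 ± 9.20 to 176 ± 7.77 CPM (-0.45 ± 0.07, adjusted p = 7.30e-05), and Gata4 (-0.45 ± 0.06), Sox7 (-0.47 ± 0.07) and Pdgfra (-0.33 ± 0.06) fell as well, while Sox17 was -0.28 ± 0.11 (adjusted p = 0.184). Nanog (0.09 ± 0.07), Pou5f1 (-0.01 ± 0.06) and Sox2 (-0.02 ± 0.07) did not pass the test; Pou5f1 became 0.01 with library totals. Interferon-induced genes rose, among them the ubiquitin-like modifier Isg15 from 1.24 ± 0.351 to 13.2 ± 1.24 CPM (3.42 ± 0.28), Ifi44 (3.73 ± 0.41) and Ifit1 (3.46 ± 0.42). In all, 518 of 13115 genes changed, 329 rising and 189 falling, and 40 rose and 2 fell by at least 1 log2 unit.

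Of the interferon response genes, 10 rose and 0 fell of 14 tested (13 and 0 adjusted over the list alone), median 2.06 (adjusted p = 4.91e-39, and adjusted p = 0.0855 with an estimated correlation). Feeder fibroblast markers stood at 0.265% and 0.252% of WT and 0.363% and 0.382% of cKO counts. All 12 markers rose (median 0.52, adjusted p = 8.18e-39, and adjusted p = 0.0855 with an estimated correlation), with Col3a1 at 0.54 and Col1a1 at 0.47. Of the p53 targets, 2 rose and 0 fell of 15 tested (10 and 0 adjusted over the list alone), median 0.24 (adjusted p = 3.53e-08, and adjusted p = 0.132 with an estimated correlation), Cdkn1a at 0.44. Of the PrE regulators, 8 fell and 0 rose of 12 tested (10 and 0 adjusted over the list alone), median -0.40 (adjusted p = 2.49e-20, and adjusted p = 0.0855 with an estimated correlation), Dab2 at -0.53. Of the basement membrane genes, 9 fell and 1 rose of 14 tested (11 and 2 adjusted over the list alone), median -0.27 (adjusted p = 1.66e-13, and adjusted p = 0.244 with an estimated correlation), Lama1 at -0.44 and Col4a1 at -0.39. Of the visceral endoderm genes, 4 fell and 0 rose of 12 tested (5 and 0 adjusted over the list alone), median -0.48 (adjusted p = 5.29e-13, and adjusted p = 0.103 with an estimated correlation), Lrp2 at -0.72 ± 0.05 and Cubn at -0.57. The anterior visceral endoderm list was called lower (2 of 6 fell, median -0.11; adjusted p = 0.0233, and adjusted p = 0.376 with an estimated correlation). The trophoblast list was called higher (2 of 14 rose, median 0.43; adjusted p = 0.00584, and adjusted p = 0.303 with an estimated correlation). Glycolysis and hypoxia genes were lower (2 of 13 fell, median -0.15; adjusted p = 3.24e-06, and adjusted p = 0.380 with an estimated correlation). Ribosomal proteins were higher (1 of 83 rose, median 0.06; adjusted p = 0.00240, and adjusted p = 0.692 with an estimated correlation). Naive (-0.08, adjusted p = 0.0952), core pluripotency (-0.02, adjusted p = 0.0952) and proliferation genes (-0.03, adjusted p = 0.1201) were not.

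By the naming rule the largest rises were Lgals3bp (1.23 ± 0.13), a secreted binding partner of galectins, Rnf213 (1.17), Helz2 (1.08), Syt11 (1.04), the chemokine genes Ccl2 (0.98) and Cxcl1 (0.87) and Msrb3 (0.86). The largest falls were the chloride channel family members Clic6 (-1.07 ± 0.18) and Clic5 (-0.96), the Nodal inhibitor gene Lefty2 (-0.92), Cables1 (-0.84), Aldh1l1 (-0.80), the cubilin partner gene Amn (-0.76), Aqp8 (-0.76) and Pga5 (-0.73). Syt11 lost its call without cKO replicate 2 (0.69, adjusted p = 0.13), Clic5 without WT replicate 2 (-0.75, adjusted p = 0.055), and Pga5 without WT replicate 2 (-0.53) or cKO replicate 1 (-0.67). With ribosomal scaling the split was 143 rising and 146 falling.

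In the libraries labelled siIgf2bp3, Igf2bp3 counts were not lower than in siNC (106 ± 10.3 to 114 ± 4.10 CPM, 0.11 ± 0.11, adjusted p = 0.577), so the directions below are those of the labels. PrE genes fell: Gata6 from 196 ± 30.1 to 100.4 ± 1.495 CPM (-0.96 ± 0.12), Gata4 (-1.19 ± 0.12), Sox17 (-1.29 ± 0.20), Sox7 (-1.21 ± 0.11) and Pdgfra (-0.99 ± 0.12). Nanog rose from 231 ± 7.99 to 329 ± 5.50 CPM (0.51 ± 0.09), and Pou5f1 (-0.07 ± 0.10) and Sox2 (0.03 ± 0.16) did not pass. The type IV collagen genes Col4a1 (-1.59 ± 0.11) and Col4a2 (-1.65 ± 0.13) fell by 3.01- and 3.15-fold. In all, 945 of 12918 genes changed, 361 rising and 584 falling.

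Of the basement membrane genes, 12 fell and 0 rose of 14 tested (12 and 1 adjusted over the list alone), median -1.15 (adjusted p = 8.54e-43, and adjusted p = 0.117 with an estimated correlation). Lamb1 was at -1.44, Lama1 at -1.31 and the matrix protein gene Sparc at -1.15. Of the PrE regulators, 10 fell and 0 rose of 12 tested (11 and 1 adjusted over the list alone), median -0.99 (adjusted p = 9.72e-18, and adjusted p = 0.146 with an estimated correlation). Visceral endoderm genes were lower (3 of 11 fell, median -0.74; adjusted p = 7.35e-07, and adjusted p = 0.216 with an estimated correlation), Cubn at -1.12 and Amn at -1.90. Parietal endoderm genes were lower as well (5 of 10 fell, median -0.61; adjusted p = 1.32e-06, and adjusted p = 0.216 with an estimated correlation). Immediate early genes fell, 8 of 14 with 1 rising (median -0.64; adjusted p = 6.23e-11, and adjusted p = 0.247 with an estimated correlation), with the zinc finger genes Egr2 at -2.27 ± 0.19 and Egr1 at -0.76 and Fos at -1.01. Stress response genes were lower too (8 fell and 1 rose of 14, median -0.42; adjusted p = 7.90e-05, and adjusted p = 0.237 with an estimated correlation), Herpud1 at -0.89 and Ddit4 at -0.77.

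Of the naive pluripotency genes, 5 rose and 0 fell of 16 tested (5 and 1 adjusted over the list alone), median 0.21 (adjusted p = 0.00356, and adjusted p = 0.247 with an estimated correlation), with Tfcp2l1 at 0.55 and Zfp42 at 0.43. Core pluripotency genes were higher (4 of 10 rose, median 0.18; adjusted p = 0.00521, and adjusted p = 0.247 with an estimated correlation), with L1td1 at 0.60 and Tdgf1 at 0.57. So were FGF/ERK targets (4 of 12 rose, median 0.25; adjusted p = 0.00211, and adjusted p = 0.247 with an estimated correlation), with Spry4 at 0.76 and Etv5 at 0.54. Nanog, Tfcp2l1, Zfp42, Tdgf1, L1td1 and Etv5 each lost the call without siIgf2bp3 replicate 1 (0.51, 0.55, 0.38, 0.56, 0.56 and 0.55) and without replicate 2 (0.47, 0.51, 0.44, 0.53, 0.60 and 0.49). Mitochondrially encoded transcripts stood at 0.389% and 0.538% of siNC and 0.793% and 0.696% of siIgf2bp3 counts. Of these genes, 6 rose and 0 fell of 9 tested (7 and 0 adjusted over the list alone), median 0.86 (adjusted p = 9.13e-09, and adjusted p = 0.356 with an estimated correlation). The 2-cell-like list was called higher (1 of 9 rose, median 0.75; adjusted p = 0.00128, and adjusted p = 0.247 with an estimated correlation). Feeder markers were too (3 of 12 rose, median 0.29; adjusted p = 0.00763, and adjusted p = 0.247 with an estimated correlation). Sox2 became -0.23 or 0.34 without siNC replicate 2 or 1. Changes in this table followed GC content (Spearman's rho -0.454, against 0.10 for Virma and -0.04 for Mettl3). Only the PrE regulators were corrected for it, and its share in the other lists was not tested.

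**Figure D1:**
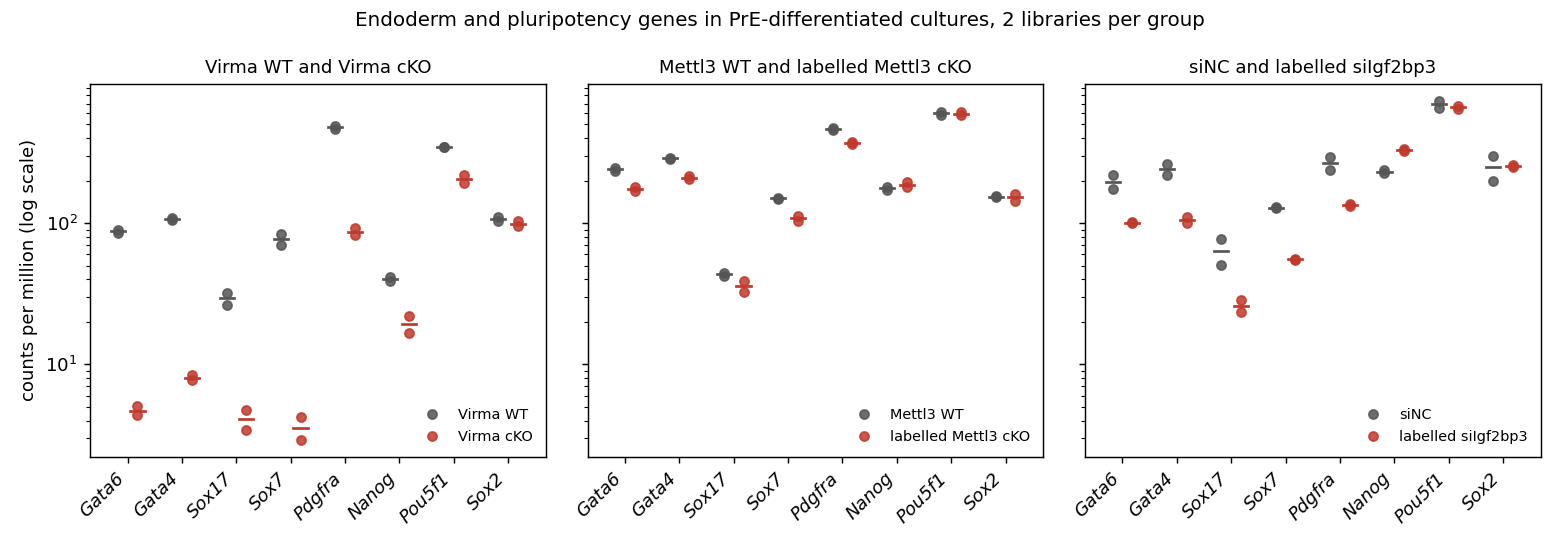
CPM (log axis) of Gata6, Gata4, Sox17, Sox7, Pdgfra, Nanog, Pou5f1 and Sox2 in PrE-induced cells of the Virma, Mettl3 and Igf2bp3 tables, with a point for each library and 2 libraries per group. Gata6 averaged 87.5 in Virma WT and 4.70 ± 0.495 CPM in Virma cKO libraries, and 239.9 and 176 in the libraries labelled Mettl3 WT and cKO.

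The responses to the Virma and Mettl3 labels were compared directly, each against the WT of its own table. The response differed for 2726 of 13872 genes, 1213 more positive with Virma and 1513 more negative. Gata6 (-3.73 ± 0.15), Gata4 (-3.24 ± 0.13), Sox7 (-3.92 ± 0.20), Sox17 (-2.53 ± 0.27) and Pdgfra (-2.09 ± 0.10) were each more negative with Virma. Of the PrE regulators, 11 of 12 differed in that direction (median -2.41; adjusted p = 3.73e-63, and adjusted p = 0.00600 with an estimated correlation). The interferon list did not pass (median -0.15 and mean 0.06, adjusted p = 0.654) and turned to 0.26 with ribosomal scaling. Without WT replicate 1 or 2 or cKO replicate 1 of the Mettl3 table, 1674, 1810 and 1633 genes differed. The split was 1742 and 991 with library totals, 940 and 1898 with RLE size factors, 732 and 1680 with DESeq2, and 3935 and 417 with ribosomal scaling.

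Calls were shared between the perturbations, which have separate controls. Virma cKO and Mettl3-labelled libraries shared 157 falling genes against 35.4 for independent lists and 239 rising genes against 49.2 (Fisher's exact test across genes, adjusted p = 2.14e-83 and 2.37e-128). Virma cKO and siIgf2bp3-labelled libraries shared 228 falling genes against 107 (adjusted p = 3.08e-33) and 75 rising genes against 55.3 (adjusted p = 0.00467), and 180 of the 483 genes called in both moved in opposite directions. Mettl3- and siIgf2bp3-labelled libraries shared 107 falling genes against 8.55 and 32 rising genes against 8.75 (adjusted p = 4.72e-95 and 2.49e-10). Genes are not independent replicates, so these p-values measure no spread between samples. All 12 feeder markers rose with both the Virma and the Mettl3 label, and a shared shift in cell mix was not excluded. Across genes, Pearson's r of the changes was 0.366, 0.0986 and 0.191 and Spearman's rho 0.343, 0.0160 and 0.186 for the 3 pairs.

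The CD140+ (PrE-E) and CD140- (EPI-E) fractions of induced cultures differed in 7172 of 12423 genes, 3510 higher and 3662 lower in PrE-E. From EPI-E to PrE-E, Cubn rose from 3.70 ± 0.391 to 5369 ± 39.7 CPM and Pdgfra from 2.95 ± 0.137 to 746 ± 21.1 (7.98 ± 0.10). Gata4 rose from 0.464 ± 0.656 to 279.6 ± 16.8 CPM (9.12 ± 0.31) and Sox7 from 0.949 ± 0.158 to 155 ± 16.6 (7.33 ± 0.21). Sox17 had no count in EPI-E and was at least 692-fold higher in PrE-E, against a floor of 3 counts in each library. Gata6 went from 1.07 ± 1.51 to 152 ± 23.8 CPM (7.23 ± 0.54), but its call was lost without either PrE-E library (7.07 and 7.36, adjusted p = 0.11 in both). Sox2 fell from 148 ± 5.18 to 1.59 ± 0.394 CPM (-6.51 ± 0.19), Nanog from 18.9 ± 2.59 to 0.193 ± 0.273 (-6.66 ± 0.70) and Pou5f1 from 577 ± 19.6 to 85.4 ± 1.93 CPM.

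All 12 PrE regulators rose (median 7.86; adjusted p = 6.20e-30, and adjusted p = 0.114 with an estimated correlation), Dab2 at 8.67. Basement membrane genes (13 rose and 1 fell of 14, median 5.55; adjusted p = 3.87e-82, and adjusted p = 0.0602 with an estimated correlation) included Col4a1, from 38.4 ± 0.916 to 10799.8 ± 16.1 CPM, and Lamb1 (6.15). Visceral endoderm genes rose (12 rose and 1 fell of 15, median 5.75 or 4.04 with genes at 0 set to their bound, adjusted p = 2.39e-10, and adjusted p = 0.327 with an estimated correlation). Parietal endoderm genes rose (9 rose and 1 fell of 10, median 3.97, adjusted p = 1.43e-12, and adjusted p = 0.257 with an estimated correlation). Besides Sox17, by the naming rule the largest rises of genes with no EPI-E count were Habp2 (at least 596-fold), the calcium-binding protein gene S100g (551), Egflam (417), the protease gene Ctsh (355), Cited1 (351), Hs3st1 (318) and the Wnt inhibitor gene Dkk1 (307).

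Formative and primed epiblast genes all fell in PrE-E (15 of 15, median -4.39; adjusted p = 1.64e-11, and adjusted p = 0.114 with an estimated correlation), with Lef1 at -7.68 and the DNA methyltransferase gene Dnmt3a at -3.14. Core pluripotency genes were lower (9 fell and 1 rose of 10, median -2.19; adjusted p = 2.63e-12, and adjusted p = 0.114 with an estimated correlation), with Tdgf1 at -7.55. FGF/ERK targets were lower (9 fell and 1 rose of 12, median -2.61; adjusted p = 6.83e-04, and adjusted p = 0.257 with an estimated correlation), with the phosphatase gene Dusp6 at -5.12 and Etv5 at -4.05. The naive pluripotency list was not called (median -2.03, 5 rose and 9 fell of 16, adjusted p = 0.136): Esrrb (-7.23) and Fgf4 (-7.45) fell and Klf5 rose (2.92). Of the 2-cell-like genes, 4 fell and 0 rose of 5 tested (5 and 0 adjusted over the list alone), median -6.39 (adjusted p = 0.0345, and adjusted p = 0.331 with an estimated correlation). Zscan4d was at -6.43, and counts of the near-identical Zscan4 copies are uncertain. Ribosomal proteins were lower (56 fell and 4 rose of 83, median -0.33, adjusted p = 0.00252, and adjusted p = 0.257 with an estimated correlation). Histones were lower (25 fell and 2 rose of 58, median -0.46; adjusted p = 0.0220, and adjusted p = 0.257 with an estimated correlation). Feeder markers were 0.0403% and 0.0415% of PrE-E and 0.0225% and 0.0211% of EPI-E counts and their list was not called (median 0.95, adjusted p = 0.221), nor was the trophoblast list (median 0.66, -0.83 at the bound). With ribosomal scaling 4428 genes rose and 2786 fell, with a median over all genes of 0.23.

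In embryoids, the VE part (n = 6) was set against the EPI part (n = 6), and 8154 of 11254 genes differed, 3882 higher and 4272 lower in VE. The visceral endoderm secretory genes were high in VE. Apoa1 rose from 2.15 ± 3.14 to 1082 ± 58.5 CPM (9.07 ± 0.50), alpha-fetoprotein (Afp) from 0.402 ± 0.610 to 104 ± 11.4 (7.89 ± 0.37), and Ttr by 8.00 and Apob by 8.11 on the log2 scale. Gata6 went from 2.55 ± 1.67 to 46.3 ± 6.63 CPM (4.17 ± 0.30), Gata4 rose by 4.49, Sox17 by 3.61, Sox7 by 4.23 and Pdgfra by 4.29. Pou5f1 fell from 148 ± 9.34 to 3.33 ± 2.02 CPM (-5.45 ± 0.22) and Sox2 from 15.0 ± 4.67 to 0.0867 ± 0.135 (-7.24 ± 0.58). Nanog, with 3 or fewer counts over the VE libraries, was lower by a ratio of 978 (95% counting interval 334 to 4745).

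All 12 PrE regulators rose (median 4.2; adjusted p = 7.09e-11, and adjusted p = 0.00109 with an estimated correlation), Cited1 at 5.34 and Hnf4a at 7.27. Visceral endoderm genes rose (16 rose and 1 fell of 17, median 5.80; adjusted p = 1.14e-15, and adjusted p = 0.00109 with an estimated correlation), Cubn at 5.33 and Lrp2 at 5.14. Basement membrane genes rose (13 rose and 1 fell of 14, median 3.27; adjusted p = 6.99e-15, and adjusted p = 0.00109 with an estimated correlation), Col4a1 at 4.28. Parietal endoderm genes rose (5 rose and 1 fell of 7, median 3.23; adjusted p = 6.32e-06, and adjusted p = 0.00215 with an estimated correlation), Srgn at 4.67. Core pluripotency genes fell (8 fell and 1 rose of 10, median -2.13; adjusted p = 7.78e-11, and adjusted p = 0.00170 with an estimated correlation), with Utf1 at -2.37. Naive genes fell (10 fell and 3 rose of 15, median -1.81; adjusted p = 3.29e-04, and adjusted p = 0.00658 with an estimated correlation), with Dppa5a at -1.81. Formative genes fell (10 fell and 1 rose of 13, median -2.69; adjusted p = 4.24e-08, and adjusted p = 0.00109 with an estimated correlation), with Otx2 at -2.69. FGF/ERK targets were lower (9 fell and 1 rose of 12, median -1.87; adjusted p = 0.00138, and adjusted p = 0.0126 with an estimated correlation), with Dusp6 at -4.71. Proliferation genes were lower (9 fell and 3 rose of 14, median -0.62; adjusted p = 0.00559, and adjusted p = 0.0319 with an estimated correlation), with the replication helicase gene Mcm2 at -2.67. The 2-cell-like genes fell (7 of 8, median -9.98 or -5.60 at the bound, adjusted p = 1.60e-22, and adjusted p = 0.00109 with an estimated correlation). Zscan4d was -13.87 ± 0.15, and the copy families Eif1ad and Usp17l, counted as uncertain, had no VE count: Eif1ad15 was at least 1584-fold lower, Eif1ad7 1074, Eif1ad8 668 and Usp17lb 498, as were the hormone precursor gene Trh (547) and Fgf15 (472). Mitochondrially encoded genes were higher (9 of 12 rose, median 1.09; adjusted p = 0.00784, and adjusted p = 0.263 with an estimated correlation). Ribosomal proteins were lower (66 fell and 2 rose of 83, median -0.34, adjusted p = 2.31e-04, and adjusted p = 0.534 with an estimated correlation). Histones were lower (28 fell and 1 rose of 36, median -1.96; adjusted p = 0.0136, and adjusted p = 0.210 with an estimated correlation). With ribosomal scaling 4966 genes rose and 3225 fell, with a median over all genes of 0.27.

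Genes that separated the sorted fractions were then followed in other tables. The 2452 genes at least 1 log2 unit higher in PrE-E had a median of 1.61 between embryoid parts, with 1907 higher and 51 lower in VE of 2251 tested (adjusted p = 3.75e-48, and adjusted p = 3.66e-09 with an estimated correlation). In the perturbations their median was -0.22 with Virma (680 fell, 267 rose; adjusted p = 2.24e-05, and adjusted p = 0.0396 with an estimated correlation). It was -0.07 with the Mettl3 label (156 fell, 60 rose; adjusted p = 8.50e-07 and 0.0495) and -0.24 with the siIgf2bp3 label (423 fell, 12 rose; adjusted p = 1.14e-23 and 0.00498). The 2220 genes higher in EPI-E had a median of -2.01 in the embryoid (adjusted p = 8.40e-35, and adjusted p = 3.66e-09 with an estimated correlation). In the perturbations their medians were 0.21, 0.05 and 0.17 in the same order, with adjusted p = 0.0184, 0.0120 and 8.95e-08, and adjusted p = 0.0598, 0.0420 and 0.0337 with an estimated correlation. Without the log2 minimum the test of the EPI-E genes pointed the other way with Virma (adjusted p = 0.980) and did not pass with the Mettl3 label (adjusted p = 0.378, and adjusted p = 0.209 with an estimated correlation).

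**Figure D2:**
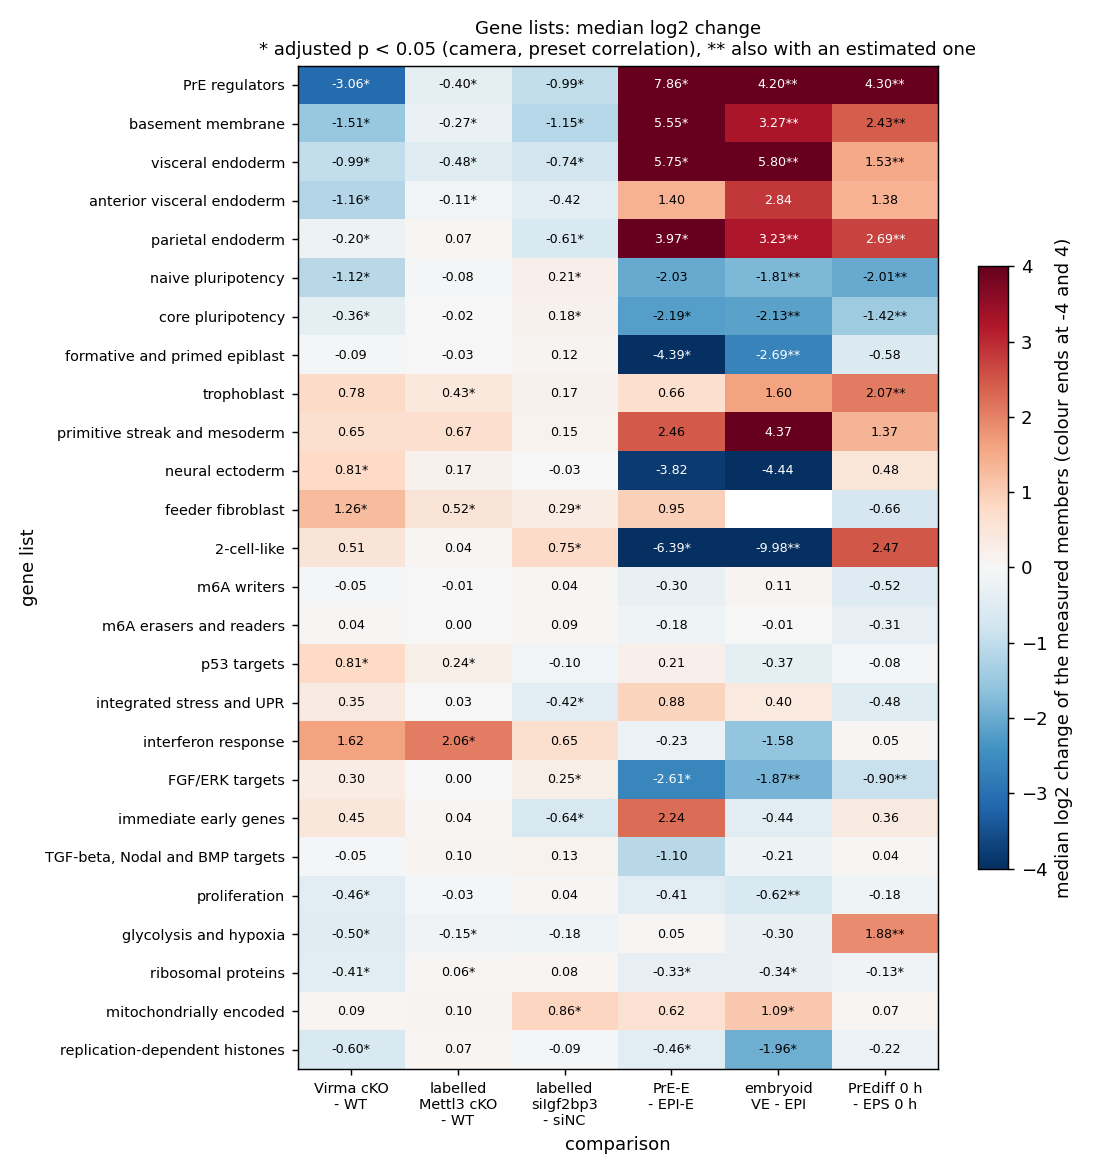
Median log2 change (colour, ending at -4 and 4) of the fixed gene lists in 6 comparisons, with an asterisk for lists with an adjusted p under 0.05 with the preset correlation and a second asterisk where an estimated correlation also gave one. The PrE regulator list had medians of -3.06, -0.40 and -0.99 in the 3 perturbation tables and 7.86 between the sorted fractions; the core pluripotency median of the Virma table turned to 0.04 with ribosomal scaling.

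Before actinomycin D, PrE-induced cells (PrEdiff) differed from EPS cells in 11376 of 14127 genes, 5310 higher and 6066 lower. Gata6 rose from 4.40 ± 0.0513 to 122 ± 4.12 CPM, Gata4 by 5.57 ± 0.07 on the log2 scale, Sox17 by 4.55 ± 0.12, Sox7 by 5.70 ± 0.09 and Pdgfra by 5.01 ± 0.06. Nanog fell from 334 ± 6.04 to 49.5 ± 0.662 CPM, Sox2 by 7.88-fold and Pou5f1 by 2.92-fold. By the naming rule the largest rise was that of Cyp26a1, an enzyme that degrades retinoic acid, from 0.442 ± 0.0215 to 230.3 ± 2.29 CPM (9.0 ± 0.09).

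PrE regulators rose (11 rose and 1 fell of 12, median 4.30, adjusted p = 2.13e-25, and adjusted p = 4.77e-05 with an estimated correlation). Basement membrane genes rose (12 rose and 2 fell of 14, median 2.43, adjusted p = 4.61e-67, and adjusted p = 1.80e-06 with an estimated correlation), Lama1 at 4.96. Visceral endoderm genes rose (10 rose and 2 fell of 14, median 1.53 or 1.29 at the bound; adjusted p = 1.85e-04, and adjusted p = 0.0488 with an estimated correlation). Parietal endoderm genes rose (8 rose and 2 fell of 10, median 2.69; adjusted p = 1.98e-08, and adjusted p = 0.00122 with an estimated correlation). Trophoblast genes rose (10 rose and 2 fell of 15, median 2.07; adjusted p = 0.0110, and adjusted p = 0.0485 with an estimated correlation). Glycolysis and hypoxia genes were higher (12 rose and 2 fell of 14, median 1.88; adjusted p = 1.98e-30, and adjusted p = 6.73e-05 with an estimated correlation), with the mitophagy receptor gene Bnip3 at 3.70 and Pgk1 at 1.99. Core pluripotency genes fell (10 of 10, median -1.42; adjusted p = 3.07e-27, and adjusted p = 4.94e-05 with an estimated correlation), Tdh at -2.96. Naive pluripotency genes fell (12 fell and 4 rose of 16, median -2.01; adjusted p = 5.69e-18, and adjusted p = 6.73e-05 with an estimated correlation). FGF/ERK targets fell (8 fell and 4 rose of 12, median -0.90; adjusted p = 0.00319, and adjusted p = 0.0312 with an estimated correlation), Etv5 at -2.33. Ribosomal proteins were called lower (59 fell and 12 rose of 83, median -0.13; adjusted p = 0.0410, and adjusted p = 0.398 with an estimated correlation), but the median was 0.05 with library totals. The m6A writers, with 6 of 8 falling (Wtap -0.79, Mettl3 -0.65), were not called as a list (adjusted p = 0.167). With library totals 6548 genes rose and 4793 fell, with a median over all genes of 0.13.

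Transcript loss after the block of transcription was measured as a log2 slope per hour relative to the average transcript, since no spike-in sets the total. In EPS cells, 5180 of the tested genes had a slope, 2570 above and 2610 below the average. Of the genes picked by the naming rule, Zfp296 fell at -1.69 ± 0.10 per hour. The phosphatase gene Dusp1 fell at -1.60 ± 0.11 (39.6, 10.6, 2.56 and 1.76 CPM at 0, 1, 2 and 3 h) and the signal gene Nodal at -1.5 ± 0.08. Sox2 fell from 311 ± 2.63 CPM at 0 h to 51.3 ± 1.71 at 3 h (-0.91 ± 0.06), whereas Nanog was -0.07 ± 0.04 (adjusted p = 0.169). Pou5f1 rose relative to the average (0.23 ± 0.08, adjusted p = 0.0338; 0.16 without either 0 h library, 0.56 ± 0.04 without the 3 h libraries and -0.01 with ribosomal scaling). Gata6 (-0.80 ± 0.07), Sox17 (-1.12 ± 0.22) and Sox7 (-0.99 ± 0.14) fell from low levels, Gata4 was -0.19 ± 0.09 (adjusted p = 0.0939) and 0.13 without the 3 h libraries, and Pdgfra -0.14 ± 0.07. Without those libraries Pdgfra (-0.32 ± 0.07, adjusted p = 7.13e-04) and Nanog (-0.07 ± 0.02, adjusted p = 0.0129) passed.

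Immediate early genes all fell (12 of 12, median -0.96; adjusted p = 1.68e-17, and adjusted p = 0.00863 with an estimated correlation). Most FGF/ERK targets fell (9 fell and 1 rose of 12, median -0.65; adjusted p = 3.69e-08, and adjusted p = 0.0317 with an estimated correlation). TGF-beta, Nodal and BMP targets fell (9 of 12, median -0.49; adjusted p = 7.67e-06, and adjusted p = 0.00447 with an estimated correlation), Bambi at -1.29. Naive pluripotency genes were lower (8 fell and 1 rose of 16, median -0.11; adjusted p = 3.17e-06, and adjusted p = 0.00447 with an estimated correlation), Klf4 at -0.89. The m6A writers were lower (6 of 8 fell, median -0.12; adjusted p = 0.00127, and adjusted p = 0.122 with an estimated correlation), Cbll1 at -0.78. PrE regulators (6 fell and 1 rose of 12, median -0.35; adjusted p = 0.00119, and adjusted p = 0.0317 with an estimated correlation) and stress response genes (9 fell and 3 rose of 14, median -0.40; adjusted p = 1.92e-04, and adjusted p = 0.108 with an estimated correlation), with Chac1 at -1.79, were lower. So were anterior visceral endoderm (4 fell and 1 rose of 7, median -0.54; adjusted p = 0.00785, and adjusted p = 0.0589 with an estimated correlation) and formative genes (9 fell and 3 rose of 14, median -0.35; adjusted p = 0.00249, and adjusted p = 0.164 with an estimated correlation). The p53 targets (5 of 15 fell, median -0.02; adjusted p = 0.0213, and adjusted p = 0.0683 with an estimated correlation) and mitochondrially encoded genes (6 fell and 1 rose of 13, median -0.22; adjusted p = 0.00701, and adjusted p = 0.189 with an estimated correlation) were also lower. Ribosomal protein genes were higher (7 of 83 rose, median 0.25; adjusted p = 3.60e-05, and adjusted p = 0.631 with an estimated correlation). Basement membrane genes were higher (8 of 14 rose, median 0.21; adjusted p = 0.00271, and adjusted p = 0.171 with an estimated correlation), a median that turned to -0.02 with ribosomal scaling. Without any 3 h libraries (chosen after seeing the data), the adjusted p was 0.382 for PrE regulators, anterior visceral endoderm and p53 targets. It was 0.513 for stress, 0.173 for mitochondrially encoded and 0.823 for basement membrane genes. Medians were -1.22 for immediate early and 0.71 for ribosomal protein genes (82 of 83 rose).

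The EPS libraries at 3 h stood apart. The ribosomal protein share of counts was 9.17%, 15.0%, 17.6% and 11.7% at 0, 1, 2 and 3 h in EPS and 9.61%, 12.8%, 15.8% and 15.4% in PrEdiff. Some rises in EPS rested on that time, those of Tnpo1 (0.35 ± 0.11; 347, 251, 269 and 736 CPM at 0, 1, 2 and 3 h), Nedd4 (0.33 ± 0.11), Acaca (0.33 ± 0.10) and Dmxl2 (0.32 ± 0.12). Their slopes were -0.15, -0.19, -0.14 and -0.25 without the 3 h libraries. They were 0.26, 0.24, 0.25 and 0.21 without EPS 3 h replicate 1 and 0.26, 0.24, 0.23 and 0.24 without replicate 2, below the threshold in each case. The lysozyme gene Lyz2 rose from 2.19 ± 0.00948 CPM at 0 h to 32.1 ± 2.11 at 3 h (1.19 ± 0.10) and Gpnmb by 0.66 ± 0.08 per hour; without 3 h they rose by 0.81 ± 0.14 and 0.27 ± 0.05. The number of EPS slopes went to 9442 without the 3 h libraries and 10043 from 3 h against 0 h alone. The split was 476 above and 3910 below with library totals, 20 and 4357 with ribosomal scaling, and 6095 and 3948 from 3 h against 0 h. The median of all genes was 0.06 in the fit used, -0.05 with totals and -0.17 with ribosomal scaling.

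In PrEdiff, where the PrE factors are expressed, their messages fell relative to the average. Sox7 went from 89.0 ± 4.39 CPM at 0 h to 7.65 ± 0.00929 at 3 h (-1.22 ± 0.08 per hour) and Sox17 from 32.9 ± 0.701 CPM at 0 h to 3.83 ± 0.460 at 3 h (-1.09 ± 0.12). Gata6 went from 122 ± 4.12 CPM at 0 h to 40.9 ± 1.58 at 3 h (-0.53 ± 0.05), and Gata4 (-0.50 ± 0.07) and Pdgfra (-0.28 ± 0.06; -0.48 ± 0.03 without 3 h) fell. Foxa2, a PrE and later endoderm factor, fell at -1.30 ± 0.12. Nanog was 0.08 ± 0.04 (adjusted p = 0.125, but -0.12 with adjusted p = 0.00176 without 3 h), Pou5f1 rose by 0.33 ± 0.07 relative to the average (-0.05 with ribosomal scaling) and Sox2 fell (-0.66 ± 0.07). Of 5210 slopes called, 2867 were above and 2343 below the average, and 3182 and 3150 were called without PrEdiff 0 h replicate 1 and 2.

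PrE regulators fell (10 of 12, median -0.39, adjusted p = 1.07e-13, and adjusted p = 6.55e-04 with an estimated correlation). Immediate early genes fell (11 of 12, median -0.62; adjusted p = 6.66e-13, and adjusted p = 0.0134 with an estimated correlation). FGF/ERK targets were lower (9 fell and 1 rose of 12, median -0.62; adjusted p = 6.94e-09, and adjusted p = 0.0194 with an estimated correlation). TGF-beta, Nodal and BMP targets were lower (8 fell and 1 rose of 12, median -0.28; adjusted p = 0.00214, and adjusted p = 0.0760 with an estimated correlation). Naive pluripotency (8 fell and 2 rose of 16, median -0.17; adjusted p = 8.09e-04, and adjusted p = 0.0760 with an estimated correlation) and formative genes (4 fell and 1 rose of 14, median -0.29; adjusted p = 0.00380, and adjusted p = 0.118 with an estimated correlation) were called lower. The m6A writer genes fell (7 of 8, median -0.13; adjusted p = 0.00105, and adjusted p = 0.118 with an estimated correlation). Ribosomal protein genes rose relative to the average (76 of 83, median 0.39; adjusted p = 1.07e-13, and adjusted p = 0.517 with an estimated correlation). Histones did too (19 rose and 1 fell of 37, median 0.40, adjusted p = 7.46e-04, and adjusted p = 0.517 with an estimated correlation). Histones were 0.0041% to 0.0073% of counts in the actinomycin D libraries, against 0.71% to 0.73% in EPSC, so their slopes rest on few counts. Glycolysis genes were called higher (9 rose and 2 fell of 14, median 0.21, -0.17 with ribosomal scaling; adjusted p = 4.10e-04, and adjusted p = 0.0134 with an estimated correlation), Pgk1 at 0.32. So were basement membrane genes (4 of 14 rose, median 0.11, -0.26 with ribosomal scaling; adjusted p = 0.0182, and adjusted p = 0.377 with an estimated correlation). Feeder markers were called higher (6 of 12 rose, median 0.15, -0.23 with ribosomal scaling; adjusted p = 0.0299, and adjusted p = 0.507 with an estimated correlation). Without the 3 h libraries these 3 lists lost the call (adjusted p = 0.0504, 0.854 and 0.854), as did the TGF-beta (0.0504) and formative lists (0.209). The median of all genes was 0.02, -0.12 with library totals and -0.36 with ribosomal scaling, which gave 533 above and 4805 below, and 2 and 9175.

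Slopes of the 2 states were compared directly because loss in 1 state and not in the other is no evidence of a difference. They differed for 180 genes at an adjusted p under 0.05, against 1730 at an unadjusted p under 0.05; 160 slopes were higher in PrEdiff and 20 lower. None of the 8 fixed genes passed. Gata6 was 0.27 ± 0.09 (adjusted p = 0.212), Gata4 -0.30 ± 0.11 (0.247), Sox17 0.03 ± 0.28 and Sox7 -0.23 ± 0.17. Pdgfra was -0.14 ± 0.09, Nanog 0.15 ± 0.05, Pou5f1 0.10 ± 0.11 and Sox2 0.26 ± 0.09 (adjusted p = 0.248). Klf2 (0.72 ± 0.16), the kinase gene Pim3 (0.65 ± 0.09), Lefty1 (0.63 ± 0.14), Nck1 (0.53 ± 0.08) and Bambi (0.66 ± 0.11) had higher slopes in PrEdiff. Without the 3 h libraries, 926 genes differed and Gata4 (-0.60 ± 0.10, adjusted p = 0.00690) and Sox2 (0.33 ± 0.08, adjusted p = 0.0316) passed, as did Pou5f1, with its sign turned (-0.20 ± 0.06, adjusted p = 0.0443). Klf2 (0.24 ± 0.13, adjusted p = 0.248), Pim3 (0.33 ± 0.11, adjusted p = 0.0661) and Nck1 (0.31 ± 0.10, adjusted p = 0.0725) then did not, while Lefty1 and Bambi did. As a list, PrE regulators did not differ (median -0.08, adjusted p = 0.572). Immediate early genes (median 0.39; adjusted p = 6.95e-11, and adjusted p = 0.0167 with an estimated correlation) and stress response genes (0.19; adjusted p = 3.32e-10, and adjusted p = 0.0386 with an estimated correlation) were called with higher slopes in PrEdiff. Of their members 4 of 12 and 2 of 14 passed, and 0 of each with ribosomal scaling, where the medians were 0.26 and 0.05. Without the 3 h libraries the stress list lost its call (adjusted p = 0.344). Leaving out EPS 3 h replicate 1 or 2 gave 105 and 95 genes, PrEdiff 0 h replicate 1 or 2 gave 96 and 92, and PrEdiff 3 h replicate 1 or 2 gave 89 and 97. The split was 2 and 0 with ribosomal scaling, 386 and 133 with DESeq2 and 394 and 532 without the 3 h libraries.

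The genes that fell in Virma cKO libraries had slopes above the average in EPS (median 0.11; adjusted p = 0.00187, and adjusted p = 0.0557 with an estimated correlation) and in PrEdiff (0.08; adjusted p = 0.00187, and adjusted p = 0.0456 with an estimated correlation). With only genes that fell by at least 1 log2 unit the test pointed below the average (adjusted p = 0.724 and 0.286). Those that rose had medians of 0.00 and -0.03 (adjusted p = 0.00807 and 0.00697, and adjusted p = 0.373 and 0.261 with an estimated correlation), and did not pass with that minimum (adjusted p = 0.286 and 0.301). Genes that rose with the Mettl3 label had slopes above the average (median 0.15 and 0.08; adjusted p = 0.0120 and 0.0253, and adjusted p = 0.368 and 0.373 with an estimated correlation), which did not pass with the minimum (adjusted p = 0.764 and 0.859). Genes that rose with siIgf2bp3 had lower slopes in PrEdiff than in EPS (median difference -0.04; adjusted p = 0.0136, and adjusted p = 0.700 with an estimated correlation), not passing with the minimum (adjusted p = 0.724).

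**Figure D3:**
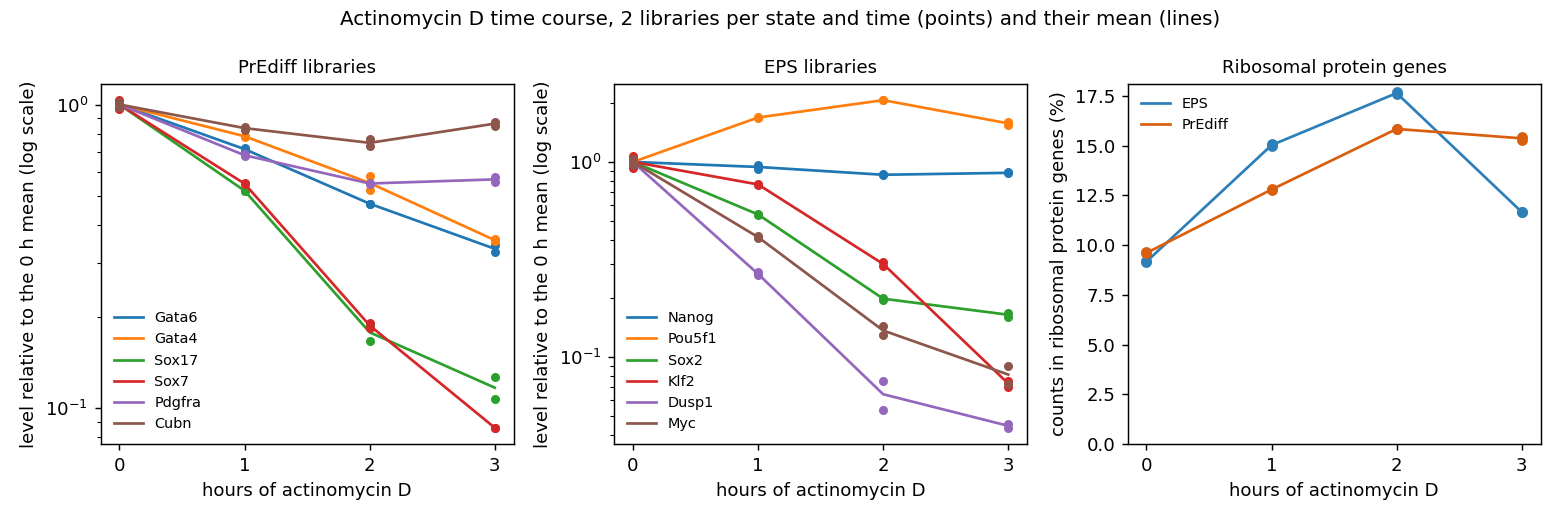
Levels of named transcripts relative to their mean at 0 h (log axis) by hours of actinomycin D in EPS and PrEdiff, with 2 libraries per time, and the ribosomal protein share of counts by hour. Sox7 in PrEdiff went from 89.0 ± 4.39 CPM at 0 h to 7.65 ± 0.00929 at 3 h, and the ribosomal share in EPS fell from 17.6% at 2 h to 11.7% at 3 h.

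Some states were held in separate tables, where table and group cannot be told apart. The same state in 2 tables, EPS at 0 h against EPSC, differed in 10230 of 13284 genes, 5169 higher and 5061 lower in EPS, or 911 and 10040 with ribosomal scaling. Histone genes led (57 of 58 lower in EPS, median -8.05 or -7.65 at the bound; adjusted p = 7.26e-36, and adjusted p = 0.430 with an estimated correlation), H4c1 going from 437 ± 4.71 to 0.213 ± 0.0701 CPM. Ribosomal proteins were higher (76 rose and 4 fell of 83, median 0.80, adjusted p = 3.34e-32, and adjusted p = 0.430 with an estimated correlation). Feeder markers were lower (12 of 12 fell, median -2.42; adjusted p = 9.93e-09, and adjusted p = 0.430 with an estimated correlation). Interferon genes were lower (13 fell and 1 rose of 14, median -3.96; adjusted p = 1.25e-04, and adjusted p = 0.430 with an estimated correlation). Against EPSC, PrE-E differed in 9369 of 12930 genes (4403 higher, 4966 lower), with Gata6 from 5.56 ± 0.0196 to 181 ± 24.5 CPM, Pdgfra from 17.1 ± 1.61 to 891 ± 44.5, Sox17 at 8.00 and Nanog at -10.09. All 12 PrE regulators rose (median 5.90; adjusted p = 2.77e-18, and adjusted p = 0.265 with an estimated correlation). Naive genes were lower (14 fell and 2 rose of 16, median -3.60; adjusted p = 5.47e-14, and adjusted p = 0.265 with an estimated correlation). Feeder markers were again lower (12 of 12 fell, median -1.75; adjusted p = 4.27e-04, and adjusted p = 0.293 with an estimated correlation). EPI-E differed from EPSC in 8469 of 12940 genes, 4201 higher and 4268 lower, or 3353 and 5508 with ribosomal scaling. Nanog went from 237 ± 5.11 to 24.2 ± 3.22 CPM, and Dnmt3a (2.56) and Dnmt3b (2.10) rose. Formative genes were higher (12 rose and 2 fell of 15, median 2.25; adjusted p = 1.22e-04, and adjusted p = 0.468 with an estimated correlation), and naive genes were lower (13 fell and 2 rose of 16, median -2.32; adjusted p = 1.30e-12, and adjusted p = 0.305 with an estimated correlation). Feeder markers (12 of 12 fell, median -2.68; adjusted p = 1.99e-09, and adjusted p = 0.305 with an estimated correlation) and immediate early genes (14 of 14 fell, median -2.21; adjusted p = 1.23e-04, and adjusted p = 0.468 with an estimated correlation) fell. Pou5f1 was 0.34 in EPI-E, -0.30 with library totals and -0.40 with EPS 0 h in place of EPSC. With library totals the splits were 2940 and 6889 for PrE-E and 2406 and 6926 for EPI-E, with medians over all genes of -0.77 and -0.71.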

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

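All tests of explanations in this part were chosen after the results they bear on were seen, including the bounds that decide them; the comparisons themselves were planned.

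The responses to the Virma and Mettl3 labels differed for 2726 genes by a test of the interaction. More positive with Virma were Trp53rkb 2.36, Slc48a1 2.21, Ccdc92b 2.11, Ppp1r16a 2.01, Hyal2 1.99, Dnah10 1.97, Tpgs1 1.96, Tpst2 1.96 and Col3a1 0.90 (log2 differences). More negative were Hesx1 -5.32, Aqp8 -4.47, Tcf23 -4.47, Amn -4.40, Srgn -4.35, Tfec -4.33, Cubn -4.15, Sox7 -3.92, Lama1 -3.84, Gata6 -3.73, Gata4 -3.24, Sox17 -2.53, Lamc1 -2.10, Pdgfra -2.09, Klf5 -1.41, Nanog -1.11 and Pou5f1 -0.71. Median differences of called lists were -2.41 for PrE regulators, -1.16 for basement membrane, -0.93 for visceral, -0.94 for anterior visceral and -0.36 for parietal endoderm, -1.09 for naive and -0.16 for core pluripotency, -0.42 for proliferation, -0.32 for glycolysis, -0.42 for ribosomal proteins and -0.68 for histones, and 0.79 for feeder markers and 0.67 for p53 targets. With an estimated correlation the anterior visceral, glycolysis, ribosomal, histone and p53 lists lost the call (adjusted p = 0.0571 to 0.0852). With ribosomal scaling the parietal, core and glycolysis medians turned to 0.05, 0.26 and 0.09.

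PrE regulators were lower in all 3 perturbation tables, on average by -3.13 ± 0.31 (Virma), -0.43 ± 0.06 (Mettl3 label) and -0.87 ± 0.14 (siIgf2bp3 label; SE over 12 genes), while feeder markers were higher by 1.24, 0.54 and 0.39. A larger share of feeder cells would dilute core pluripotency genes alike, yet PrE regulators lay below them by -2.53 ± 0.38, -0.36 ± 0.07 and -1.11 ± 0.17, and after removing a loess trend on gene length and GC content the means were -3.29 ± 0.31, -0.46 ± 0.06 and -0.75 ± 0.14, so neither accounts for the pattern alone. Fewer PrE cells with unchanged levels in each would lower genes specific to PrE-E by a common amount: 60% of 20 such genes (Virma), 21.9% of 32 (Mettl3 label) and 17.2% of 29 (siIgf2bp3 label) lay over 2 SE from their median, where at most 10% would fit and over 50% would argue against it. With Virma only 5.81% of the level was left at the median, near the 5% allowed from other cells, which voids the test there, and in the other tables the shares lie between the bounds; 4 definitions of specific genes were tried, the 5% limit was kept after seeing them, and the voiding rule was added after the 60% was seen. Lower numbers of PrE cells and lower messages in each therefore cannot be told apart, and the labelled genotype or siRNA stays open as a biological candidate explanation.

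The slopes of PrEdiff and EPS differed for 180 genes by a test of the difference. They were higher in PrEdiff for Klf2 0.72, Bambi 0.66, Pim3 0.65, Lefty1 0.63, Nck1 0.53, Atf3 0.53, Gprc5a 0.49, Cln8 0.49, Zswim1 0.48, Herpud1 0.45, Cdkn1a 0.37, Zfp42 0.37, Ier2 0.31 and Klf4 0.30, and lower for Vangl1 -0.29, Lrrc45 -0.29, Gask1b -0.28, Pop1 -0.28, Sfpq -0.25, Pyroxd1 -0.25, Ogdh -0.24 and Zfp692 -0.22 (log2 per hour). Without the 3 h libraries 65 of the 180 stayed called, and with ribosomal scaling 2 did. Without EPS 3 h replicate 1, Klf2 (0.62), Lefty1 (0.55), Vangl1 (-0.27), Sfpq (-0.22) and Atf3 (0.47) were not called. Median differences of called lists were 0.39 for immediate early genes, 0.20 for histones (on few counts), 0.19 for stress response, 0.18 for TGF-beta targets, 0.14 for ribosomal proteins, 0.12 for mitochondrially encoded genes, 0.11 for naive pluripotency, 0.0878 for p53 targets, 0.0842 for anterior visceral endoderm and 0.0597 for glycolysis. With an estimated correlation only the immediate early, stress, TGF-beta and p53 lists stayed called, and the others had adjusted p = 0.0575 to 0.858. The mitochondrial, naive, p53, anterior visceral endoderm and glycolysis medians turned to -0.02, -0.03, -0.05, -0.07 and -0.09 with ribosomal scaling, and the ribosomal median to -0.20 without the 3 h libraries (adjusted p = 9.29e-19). Without those libraries the histone, stress, naive, p53 and glycolysis lists lost the call (adjusted p = 0.104 to 0.868), with medians of -0.13, 0.0785, -0.04, 0.0257 and -0.01.

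Exchanging state labels within time points gave as many genes in 6 of 100 drawn exchanges of 648 possible, the real one included, with 8269 as the highest other, and as many lists (10) in 25 of 100, with 12 as the highest other. The states differed in 11376 genes at 0 h, and exchanges carry that difference into the slopes (the 5 others with as many genes swapped both 3 h labels and kept both at 0 h) or into the spread. They say nothing about chance. In the embryoid, only the real split of 100 drawn (462 possible) gave the 8154 genes called. The others, which mix the parts, gave 0. This excludes chance for the number of genes only if libraries are separate cultures. For the embryoid's 13 called lists, 6 of 100 gave as many with 15 as the highest other, so that count alone does not exclude chance. The 5 others kept 4 or 5 libraries of a part together and so kept part of the difference, while the 42 splits that parted both evenly gave at most 2 lists. Both the PrE-E and the EPI-E set were called in 58 of 100 splits, with 2 as the highest other; a count that cannot pass 2 says nothing about chance. The rules that void the exchanges and the count of sets were added after the counts were seen.

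In EPS, changes from 2 h to 3 h ran against those from 0 h to 2 h across 8778 genes (r = -0.571, or -0.574 with the 2 h libraries exchanged), against -0.135 and -0.102 in PrEdiff. Both changes followed transcript length, with Spearman's rho of -0.652 and then 0.665 in EPS and -0.638 and then 0.350 in PrEdiff. With the length and GC trend removed the correlation was -0.248 (-0.253 exchanged) in EPS and 0.156 (0.18) in PrEdiff, below a bound set after the value was seen, so that trend may be part of the pattern and not all of it. If the 3 h libraries had been taken at 0 h or 1 h, immediate early genes would not lie below their 1 h level, yet 9 of 9 had both 3 h libraries below both 1 h libraries. No biological explanation was tested.

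Single embryoid libraries stood apart from the other 5 of their group in 7 of 79 sets of values tested, where chance gives about 1 in 20. In VE, Apob was at 115 CPM in replicate 6 (nearest 149.8) and Afp at 126 in replicate 3 (nearest 106). In EPI, the total count was 14824609 in replicate 3 (nearest 10052480), Apoa1 was at 8.16 CPM in replicate 2 (nearest 3.06), Eif1ad15 at 470.0 in replicate 3 (nearest 603), Eif1ad8 at 326 in replicate 1 (nearest 254) and Sox2 at 23.8 in replicate 1 (nearest 15.95). Without any of these libraries in turn 8115 to 8220 genes were called, 7861 to 7941 of them among the 8154.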

How the results depend on the processing

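The alternatives chosen after seeing the data are named with the processing above, and the others were planned. Of the log2 changes of named genes, 446 had the same direction and side of the threshold with RLE size factors, 438 with DESeq2, 447 with the filter of 1 CPM, 441 without a low-count filter, 427 with library totals and 396 with ribosomal scaling; 3209 did when a library was left out, 163 lost and 9 gained a call, and 15 changed sign. Where groups had 2 libraries, the lone library left was assumed to vary like the other groups. Of list and set tests together, 256 stayed on their side of the threshold and 113 lost a call with an estimated correlation. Where no value below shows it, the cause was not tested.

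Numbers of called genes moved over 1.5 times as follows. Ribosomal scaling gave 289 for the Mettl3 label (518 in the fit used), 9177 for PrEdiff slopes (5210), 2 for the slope difference (180) and 4352 for the Virma and Mettl3 difference (2726). DESeq2 gave 212 for the Mettl3 label and 519 for the slope difference, and the fit without a low-count filter 1699 for siIgf2bp3 (945). Without the 3 h libraries, 9442 EPS slopes (5180), 8381 PrEdiff slopes and 926 differences were called; from 3 h against 0 h alone 10043, 9552 and 6268; without the EPS 3 h libraries 8748 EPS slopes and 4140 differences; and from 2 h against 0 h 4478 differences.

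With the replicate block, 1467 genes were called for siIgf2bp3 and 100 for the slope difference; 3 list tests gained a call (mitochondrially encoded genes between the sorted fractions, adjusted p = 0.0416; anterior visceral endoderm in the embryoid, 0.0141; feeder markers in EPS slopes, 0.0487), and no list lost one. It gave 4285 genes for Virma, 407 for the Mettl3 label, 6746 for the sorted fractions, 7947 for the embryoid and 11382 for the states at 0 h. Same-numbered libraries did not deviate together (correlations of 0.00191 for Virma, -0.267 for Mettl3, -0.102 for Igf2bp3, 0.0165 for the sorted cells and -0.0110 to 0.0288 in the embryoid, where 1 of 6 numbers correlated best with itself), so the numbers were not taken as pairs. A crossed pairing called 1421 genes for the Mettl3 label and 1979 for siIgf2bp3.

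With an estimated correlation the number of called lists went from 14 to 0 for Virma, 10 to 0 for the Mettl3 label, 12 to 0 for siIgf2bp3, 10 to 0 between the sorted fractions, 13 to 5 for EPS slopes, 12 to 4 for PrEdiff slopes, 10 to 4 for their difference, 13 to 8 for the Virma and Mettl3 difference, and to 0 for PrE-E (12), EPI-E (6) and EPS 0 h (11) against EPSC. Of 15 called sets, 8 were called with an estimated correlation and 6 with the other log2 minimum, where the set higher in EPI-E turned in Virma cKO (adjusted p = 0.980) and the set lower in Virma cKO turned in EPS (0.724) and PrEdiff slopes (0.286). Shared calls with a log2 change of at least 1 numbered 1 falling and 6 rising for Virma and Mettl3 (of 2 and 29 with Mettl3) and 54 and 12 for Virma and siIgf2bp3. Mettl3 and siIgf2bp3 shared 0 and 0, which says nothing, as only 1 and 17 genes with Mettl3 could be shared. With DESeq2 calls they were 81 and 104, 208 and 40, and 55 and 18.

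Signs turned with library totals for Sox2 in Virma cKO (0.0735) and in the Virma and Mettl3 difference (0.0778), Pou5f1 in the Mettl3 label (0.00934) and in EPI-E against EPSC (-0.30), and Nanog in PrEdiff slopes (-0.0671). With ribosomal scaling they turned for Sox2 in Virma cKO (0.30) and in the difference of responses (0.36), for Pou5f1 in EPS slopes (-0.0100), PrEdiff slopes (-0.0518) and their difference (-0.0418), for Nanog (-0.30), Pgk1 (-0.0606), Bnip3 (-0.13) and Rpl15 (-0.0746) in PrEdiff slopes, and for Nanog (-0.41), Pou5f1 (-0.17) and Sox2 (-0.73) in EPS 0 h against EPSC; the ribosomal share of PrEdiff counts was 9.61% at 0 h and 15.4% at 3 h. Without the 3 h libraries the EPS slopes of Tnpo1 (-0.15), Nedd4 (-0.19), Acaca (-0.14), Dmxl2 (-0.25) and Gata4 (0.13), the PrEdiff slope of Nanog (-0.12) and the differences of Gata6 (-0.0731), Sox17 (-0.0312), Nanog (-0.0434) and Pou5f1 (-0.20) turned. Without the EPS 3 h libraries those of Tnpo1 (-0.18), Nedd4 (-0.22), Acaca (-0.17), Dmxl2 (-0.28) and Gata4 (0.0898) and the differences of Pdgfra (0.0794) and Pou5f1 (-0.20) did. Differences of Sox17 turned from 3 h against 0 h (-0.37), and those of Sox7 (0.15) and Pou5f1 (-0.25) from 2 h against 0 h. With EPS 0 h in place of EPSC, Pou5f1 (-0.40) and Col1a1 (0.93) turned in EPI-E.

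Leaving out each library in turn gave 242 to 4936 genes for siIgf2bp3, 3150 to 5466 PrEdiff slopes, 89 to 206 slope differences and 1633 to 3377 genes for the Virma and Mettl3 difference. Named genes that changed sign ranged as follows: with the Mettl3 label Pou5f1 -0.053 to 0.0317, Sox2 -0.093 to 0.0376 and Mettl3 -0.071 to 0.0306; with siIgf2bp3 Pou5f1 -0.16 to 6.41e-05, Sox2 -0.23 to 0.34 and Igf2bp3 -0.0132 to 0.21. Sox17 ranged from -0.11 to 0.17 in the slope difference and from -0.0913 to 2.99 in EPS 0 h against EPSC, and Sox2 from -0.25 to 0.0230 in the difference of responses.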

Other observations

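Levels in this part were chosen after seeing the data, as were the tests named here. Each table was scaled by itself over nearly all its genes, so a level can differ a little from that of the same gene in a fit.

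Levels of single genes differed between PrE-induced cells of the actinomycin D table and those of the perturbation tables, which were prepared apart, so table and culture cannot be told apart. Cyp26a1, the retinoic acid hydroxylase gene, was at 229.5 ± 1.87 CPM in PrEdiff at 0 h, against 6.39 in Virma WT, 9.32 in Mettl3 WT and 4.12 in siNC libraries (n = 2 each), with 164 in PrE-E and 817 ± 29.0 in embryoid VE (n = 6). Hoxb1, a hindbrain homeobox gene, was at 65.4 CPM in PrEdiff at 0 h and at 0.0435, 0.785 and 0.422 in the same 3 control groups, and was at 0 in PrE-E. Stra8, which retinoic acid induces in germ cells, was at 289 CPM against 151, 64.9 and 74.9, and at 0 in PrE-E. Aldh1a2, a retinoic acid synthesis gene, was at 1.31 CPM against 2.43, 2.23 and 0.970.

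Zscan4c, a gene of 2-cell-like cells whose near-identical copies share reads, was at 1226 ± 52.7 CPM in embryoid EPI (n = 6) and 0.0435 in embryoid VE, against 24.99 in EPI-E, 10.96 in PrEdiff at 0 h and 2.74 in EPS at 0 h (n = 2 each). From 0 h to 3 h in EPS, Lyz2 went from 2.19 to 32.1 CPM, Gpnmb from 8.93 to 37.8, Ctss from 0.400 to 3.79, Mmp12 from 0.490 to 3.04 and Mpeg1 from 0.488 to 2.45, while Csf1r went from 0.793 to 0.535, Fcer1g from 0.280 to 0.205 and C1qa from 0.208 to 0.484. Lyz2 in PrEdiff went from 2.54 to 7.40. These levels were not tested as a group.

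Interferon response genes were higher in the Mettl3-labelled libraries, by 2.01 ± 0.32 log2 units on average (SE over 14 genes), and the labels give the genotype as the biological difference. A larger share of feeder cells would raise them no more than the feeder genes, yet they exceeded these by 1.48 ± 0.32. Removing a loess trend on gene length and GC content left a mean of 1.97 ± 0.32. Both values argue against these as the whole source of the rise. Activation by double-stranded RNA or by an infection of the culture was not tested and may stay open. The deletion itself stays open too, but its target gene was not lower in counts. The interferon list also differed between EPS at 0 h and EPSC, by more at the median and with no genotype in the labels. It was not called between the Virma and Mettl3 responses, so the rise is not shown to be specific to Mettl3.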
